A study of Danio rerio with 13 samples.

How the data were processed

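Gene expression was measured by RNA sequencing in 13 libraries of zebrafish larvae of the Tg(fli1:EGFP) line, a transgenic line whose fli1 promoter drives EGFP in endothelial cells. The labels give 5 untreated wild-type libraries, 3 libraries of larvae homozygous for a CRISPR knockout of aldh3b1, and 5 libraries of wild-type larvae treated with 2-HD. The labels do not spell out 2-HD, and they give no dose, duration, larval age, clutch or batch. They name no group treated with vehicle alone, so effects of a vehicle or of handling cannot be told apart from those of 2-HD. Libraries are named here by their group and the number in their description label. For 1 wild-type library the number in the title (1) differs from that in the description (3), and the description, which also names the column of the table, was used. Nothing in the labels says whether the libraries of a group came from separate pools of larvae, so p-values measure only the spread between these samples, which may be technical.

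The values deposited by the authors are whole-number counts of reads per gene, not normalized. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made for BGISEQ-500 sequencing. Per the submitters' processing notes, the tools were Trim Galore 0.6.7, HISAT2 2.2.1 and featureCounts 2.0.1, and the genome build was GRCz11. The annotation, the strand setting and the treatment of multiply mapped reads were not given in the sources used here. Counts of paralogues, overlapping genes and antisense partners are therefore uncertain. The table has 32417 entries with 31681 distinct symbols, and 1296 entries share their symbol with another. Such entries were kept apart, and a later entry of a shared symbol is called the second row of that name. A further 18 entries carry a spreadsheet date in place of a symbol. Each entry carried a name, so no counts were set aside.

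The total per library ranged from 17975289 to 19482661 counts. At this depth 3 counts, the limit that a count of 0 allows, correspond to 0.154 to 0.167 CPM, counts scaled by library size. This limit covers counting error only. Within-group pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 4.91 to 26.1, so no library was treated as a duplicate of another.

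Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr and its minimum count of 10, which left 22158 genes. Library sizes were scaled with TMM factors, and CPM values use those factors. A quasi-likelihood model with 3 group means was fitted to all 13 libraries, so that the groups share 1 estimate of spread, and the biological coefficient of variation was 0.151. The 3 contrasts were knockout minus wild type, 2-HD minus wild type and knockout minus 2-HD. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors were computed from the fitted log2 fold change and its F statistic. Adjusted p-values of single genes come from this test unless another tool is named, and a gene is said to rise or fall only where it was called.

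The groups, tests, alternatives, 43 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover metabolism, stress responses, the retina and other tissues, cell types and RNA quality. Each was tested with camera from limma 3.58.1, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 43 lists in each contrast. Beside the test stand the members called over all genes and those called when adjusted over the list alone. No list remained called in any contrast when camera estimated the correlation from the data. Principal components were computed on log2 CPM with a prior count of 2.

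The naming rule took aldh3b1 and, for each comparison with wild type, the 10 largest rises and the 10 largest falls. These were taken among called genes with an average log2 CPM of at least 1, no overlap between the libraries of the 2 groups, and a symbol that is not a placeholder. For knockout against 2-HD it took 5 in each direction. From each list called or with at least 3 called members it took up to 3 called members with the smallest adjusted p, and it took all called aldehyde dehydrogenases. List members are named here only for the lists described, and 2 genes that the rule took are not reported here.

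The overlap between the comparisons that share the wild-type libraries was set against 20 simulated data sets without changes and against the 20 ways of splitting those libraries 2 and 3. The steps were tested on simulated counts with 200 changed genes among 22158. For knockout against wild type, 34.3% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 84.8% of those changed 4-fold were recovered, and 9.56% of calls were false. For 2-HD against wild type these shares were 61.2%, 83.6% and 93.9%, with 5.36% of calls false. For knockout against 2-HD they were 31.3%, 80.6% and 92.4%, with 5.56% of calls false. In each simulated comparison camera called the 1 raised list and 0 of 42 unchanged lists. Simulated genes were drawn independently and these lists at random, so this could not show false calls of lists whose genes vary together. The correlations that camera estimated for the real lists reached 0.671.

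Alternatives were other scalings (RLE and upper-quartile factors), other filters, DESeq2 1.42.0, limma-voom with sample quality weights, fits with only the groups compared, a test against a 1.2-fold change, and 1 surrogate variable from sva 3.50.0. Each library was also left out in turn, and the number in the description label was entered as a replicate block. For the lists, camera with an estimated correlation and fry were run. Counts without wild type replicate 14 and 2-HD replicate 1 together, and without the 200 genes nearest aldh3b1, were added after seeing the data, as was the test of these neighbouring genes. The table of RefSeq genes used for gene order is of assembly GRCz12tu, whereas the counts were made on GRCz11, so it served only to find which genes neighbour each other, and 81.5% of tested genes were matched by symbol or synonym.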

Results

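RNA sequencing counts were compared between untreated wild-type zebrafish larvae (5 libraries), larvae labelled as homozygous for an aldh3b1 knockout (3 libraries) and wild-type larvae treated with 2-HD (5 libraries). The series concerns the function of aldh3b1, an aldehyde dehydrogenase gene, in diabetic retinopathy. The knockout was set against wild type to show what differs in larvae with that label, and the treated larvae were set against the same wild types. Libraries held 17975289 to 19009200 counts in wild type, 19066393 to 19332225 in the knockout and 19339056 to 19482661 with 2-HD. These ranges differ little in size but do not overlap.

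The targeted gene was read in every library. Expression of aldh3b1 was 6.10 ± 1.22 CPM (SD, n = 5) in wild type and 5.19 ± 0.608 CPM (SD, n = 3) in the knockout, from 86 to 129 counts per library in these 8 libraries. The log2 fold change of the knockout was -0.23 (SE 0.19, 95% interval -0.63 to 0.17), which was not past the threshold (edgeR adjusted p = 0.474). The transcript level therefore did not separate knockout from wild-type libraries. It cannot serve as a check of their labels, since a small insertion or deletion need not lower the mRNA. With 2-HD, aldh3b1 rose to 10.15 ± 1.99 CPM (SD, n = 5), a log2 fold change of 0.73 (SE 0.16, adjusted p = 0.00179). Its log2 difference between knockout and 2-HD was -0.97 (SE 0.19, adjusted p = 0.0152). That call was lost without knockout replicate 3 (adjusted p = 0.0576) and without knockout replicate 7 (adjusted p = 0.0524).

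The first principal component held 37.7% of the variance and placed the knockout between the other groups. Wild-type libraries lay between -52.0 and -16.2 on it, knockout libraries between -9.31 and 9.86, and 2-HD libraries between 8.03 and 49.6. The second component, with 15.5% of the variance, set wild type replicate 14 (-41.6) and 2-HD replicate 1 (-53.8) apart from the other 11 libraries, which lay at -4.36 or above.

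**Figure D1:**
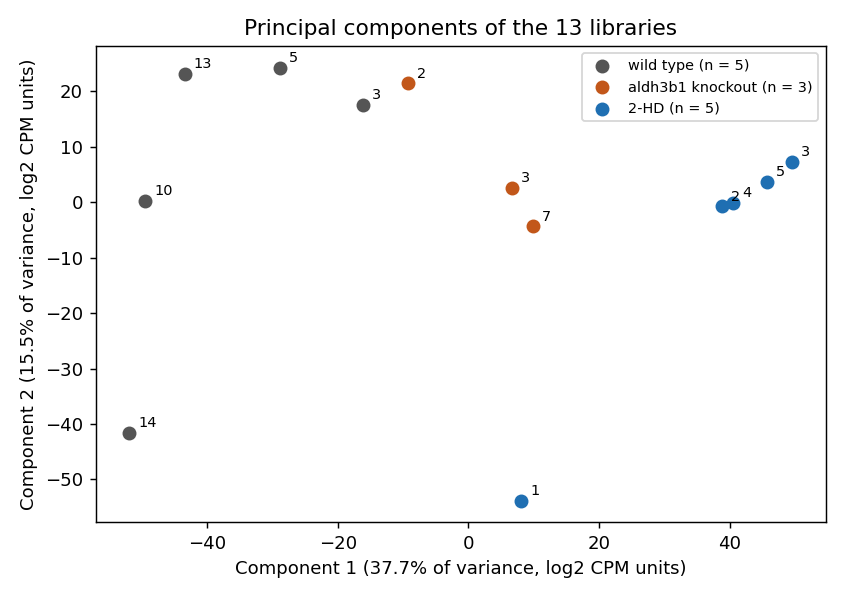
Scores of the 13 libraries on the first principal component (x axis, 37.7% of variance) and the second (y axis, 15.5%), computed on log2 CPM; each point is a library, coloured by group and marked with its number. Wild type, knockout and 2-HD follow each other along the x axis, except that knockout replicate 7 (9.86) lies past 2-HD replicate 1 (8.03). On the y axis, wild type replicate 14 and 2-HD replicate 1 lie apart at -41.6 and -53.8.

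In the knockout, 18 of 44 measured genes of the extracellular matrix, 11 of 40 of the epidermis, 5 of 22 of heart muscle and 4 of 50 of the liver were higher than in wild type, and 8 of 54 genes of photoreceptors, 5 of 82 of ribosomal proteins and 6 of 86 of oxidative phosphorylation were lower. Among called genes with a symbol that is not a placeholder, an average log2 CPM of at least 1 and no overlap between the libraries of the groups, the largest rises were those of muc13a, a membrane mucin gene, from 3.03 ± 1.91 to 13.8 ± 6.04 CPM, and of col10a1a, the collagen X gene of maturing cartilage and bone, from 17.2 ± 3.36 to 71.9 ± 39.2 CPM (SD, n = 5 and 3). Within the same limits, the largest fall was that of psmc3ip, which encodes a cofactor of meiotic recombination, from 3.90 ± 0.314 to 0.875 ± 0.217 CPM, a log2 fold change of -2.15 (SE 0.25, edgeR adjusted p = 0.00632). In all, 1322 of 22158 genes were called, 909 higher and 413 lower. Of these, 208 were more than 2-fold higher and 19 more than 2-fold lower.

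Further rises named by the rule were those of sdr42e2 (log2 fold change 1.97), the second row named smyhc2, a slow myosin heavy chain gene (1.92), foxe1, a forkhead transcription factor gene (1.79), and scpp5, of the secretory proteins of mineralised tissue (1.79). They also included and2, a structural gene of the larval fin fold (1.78), the heat-inducible chaperone gene hsp70l (1.68), casp6b.1, a caspase gene (1.6), and the homeobox gene barx2 (1.59). Falls after psmc3ip were those of fabp7b, a fatty acid binding protein gene of the brain (-1.94), the second row of the globin gene hbae1.3 (-1.48), the pyrophosphatase gene ppa1a (-1.42) and slc22a21, a solute carrier gene (-1.0). The remainder were a row named for the mitochondrial genome (-0.94) and the retinal genes samd7 (-1.07), opn1lw1, a red cone opsin gene (-0.95), cabp2a (-0.90) and fscn2a (-0.89). Adjusted p-values of these 20 genes ranged from 0.00632 (psmc3ip and casp6b.1) to 0.0486 (samd7). Both psmc3ip and casp6b.1 are among the 200 measured genes nearest aldh3b1 in the gene order of assembly GRCz12tu, and fscn2a lies on the same chromosome.

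Matrix genes formed the list with the most calls in the knockout. Of 44 measured collagen and matrix genes, 18 rose, 0 fell and 26 did not pass the test, or 27 rose when adjusted over the list alone. Examples were mmp2, a matrix metalloproteinase gene (57.5 ± 5.65 to 91.7 ± 11.3 CPM, adjusted p = 0.0101), its activator mmp14b (32.0 ± 2.38 to 45.4 ± 5.62 CPM) and the basement membrane collagen gene col18a1a (111 ± 14.9 to 162 ± 26.0 CPM). The list was called by camera (adjusted p = 9.76e-16), but not with an estimated correlation (adjusted p = 0.413). Without wild type replicate 14 and 2-HD replicate 1, 21 of the 44 genes rose.

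Epidermis and ionocyte genes also rose, with 11 of 40 higher and 0 lower (21 and 0 adjusted over the list alone) and a camera adjusted p of 1.89e-10. Among them were ppl (135 ± 20.3 to 264 ± 61.5 CPM) and evplb (119.9 ± 20.1 to 232 ± 53.8 CPM), both of the plakin family that links keratin to cell junctions, and the carbonic anhydrase gene ca15a (7.03 ± 2.22 to 15.3 ± 5.62 CPM). Of these, ppl is 1 of the 200 genes nearest aldh3b1. Cardiac muscle genes had 5 of 22 higher and 0 lower (9 and 0 adjusted over the list alone), with a camera adjusted p of 6.64e-06. They included the myosin light chain gene myl4 (11.1 ± 4.21 to 30.2 ± 7.22 CPM), the troponin gene tnnc1a (1.22 ± 0.439 to 2.96 ± 1.03 CPM) and actc1a (1.48 ± 0.208 to 16.9 ± 13.3 CPM), whose symbol stands more than once in the table. The rise of actc1a, larger than that of muc13a, rested on knockout replicates 3 and 7 (22.8 and 26.3 CPM), whereas replicate 2 had 1.64 CPM, within the wild-type range. Hepatocyte genes had 4 of 50 higher and 0 lower (17 and 0 adjusted over the list alone), with a camera adjusted p of 2.53e-10. Examples were the apolipoprotein B gene apoba (53.9 ± 17.1 to 140.0 ± 54.3 CPM), a2ml (46.7 ± 16.5 to 92.3 ± 29.9 CPM), and tdo2a of tryptophan breakdown (47.9 ± 3.97 to 62.1 ± 2.83 CPM). The adjusted p was 0.413 with an estimated correlation for each of these 3 lists. Without wild type replicate 14 and 2-HD replicate 1, 10 epidermis, 4 cardiac and 15 hepatocyte genes rose.

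Further calls of higher genes were found in other lists, of which 5 called by camera follow. Cartilage and bone had 4 of 32 (5 adjusted over the list alone), among them sp7, a transcription factor gene of bone (log2 fold change 1.28), and col11a1b (0.42). Pigment cells had 4 of 29 (7 adjusted over the list alone), among them paics, of purine synthesis (1.18), kita (0.97) and slc2a15a (0.93). Nrf2 targets and glutathione genes had 4 of 45 (6 adjusted over the list alone), among them nfe2l2a, which encodes Nrf2 itself (0.48), mgst1.1 (0.56) and abcb6a (0.87). In wild type replicate 14, abcb6a stood at 8.95 CPM, against 4.52 to 5.54 CPM in the other 4 wild-type libraries. Sphingolipid metabolism had 3 of 47 (10 adjusted over the list alone), namely galca (0.69) and the serine palmitoyltransferase genes sptlc3 (0.62) and sptlc1 (0.42). Leukocytes had 1 of 37 (1 adjusted over the list alone), the macrophage gene mpeg1.2 (1.09). None of the 5 lists had a called fall. These lists without wild type replicate 14 and 2-HD replicate 1 had 3 higher and 0 lower (cartilage and bone), 6 higher and 1 lower (pigment), 2 higher and 1 lower (Nrf2), 3 higher and 0 lower (sphingolipid) and 1 higher and 0 lower (leukocytes). Camera adjusted p-values were 0.000514, 0.00256, 0.00477, 0.00191 and 0.00957 in this order. Without knockout replicate 7 the camera calls of the Nrf2 list (0.0529) and the leukocyte list (0.0948) were lost. With an estimated correlation the adjusted p was 0.428 for cartilage and bone and 0.413 for the other 4 lists. Of the 21 aldehyde dehydrogenases measured, 1 was called, aldh4a1 (0.43, adjusted p = 0.0493), and 0 when adjusted over the list alone. As a list they were not called (camera adjusted p = 0.0832). Fatty acid synthesis genes had 3 of 30 higher and 0 lower (3 and 0 adjusted over the list alone) and were not called as a list either (camera adjusted p = 0.216).

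Photoreceptor and phototransduction genes were lower in the knockout in 8 of 54 cases and higher in 0, or lower in 30 when adjusted over the list alone (camera adjusted p = 2.26e-17). They included gngt2b, a cone transducin subunit gene (691 ± 146 to 389.9 ± 58.6 CPM), its rod counterpart gngt1 (94.3 ± 20.8 to 57.1 ± 2.52 CPM) and the rhodopsin kinase gene grk1a (49.6 ± 6.89 to 33.9 ± 4.83 CPM). Cytosolic ribosomal protein genes had 5 of 82 lower and 0 higher, or 15 lower adjusted over the list alone, among them rplp2 (-0.52) and rps25 (-0.43). That list had a camera adjusted p of 2.95e-13. Nuclear genes of oxidative phosphorylation had 6 of 86 lower and 0 higher, or 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 7.16e-08). They included cox7c (-0.32), atp5f1e (-0.39) and cox6a2 (-0.58), and cox6a2 is 1 of the 200 genes nearest aldh3b1. Neuronal genes had 2 of 43 lower, syt1a (488 ± 29.1 to 399 ± 26.8 CPM) and gap43 (-0.33), and 0 higher, or 3 lower adjusted over the list alone (camera adjusted p = 2.52e-09). The adjusted p was 0.413 with an estimated correlation for each of these 4 lists. Skeletal muscle genes went both ways, with 6 of 54 higher and 3 lower (10 and 10 adjusted over the list alone), and were not called as a list (camera adjusted p = 0.626, median -0.07 and mean 0.03 on the log2 scale). The slow myosin gene smyhc1 rose (479.7 ± 65.2 to 764 ± 79.2 CPM) and the parvalbumin gene pvalb1 fell by 0.39 on the log2 scale. Leaving out wild type replicate 14 and 2-HD replicate 1, 7 of 54 photoreceptor, 12 of 82 ribosomal protein, 7 of 85 oxidative phosphorylation and 2 of 43 neuronal genes fell, and skeletal muscle had 4 higher and 4 lower. No gene was called by edgeR, over all genes or over the list alone, among 31 genes of the unfolded protein response, 42 cell cycle genes, 24 exocrine pancreas genes and 51 proteasome genes.

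The number of knockout calls depended on single libraries and on the fit. It was 3 without knockout replicate 3 and 4 without knockout replicate 7, but 1650 without knockout replicate 2. In that last fit 1048 of the 1322 genes kept their call, so the calls rested mainly on replicates 3 and 7. It was 306 without wild type replicate 10, 398 without wild type replicate 13 and 2071 without wild type replicate 3. With only these 2 groups in the fit 102 genes were called, and DESeq2 called 2399 genes, 1347 higher and 1052 lower. Of the genes named for this comparison, psmc3ip and casp6b.1 alone were called both without knockout replicate 3 and without knockout replicate 7. All 1322 genes kept the sign of their fold change in both of these fits. That decides nothing, since the genes were chosen by their calls in the same data and the fits share all other libraries.

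**Figure D2:**
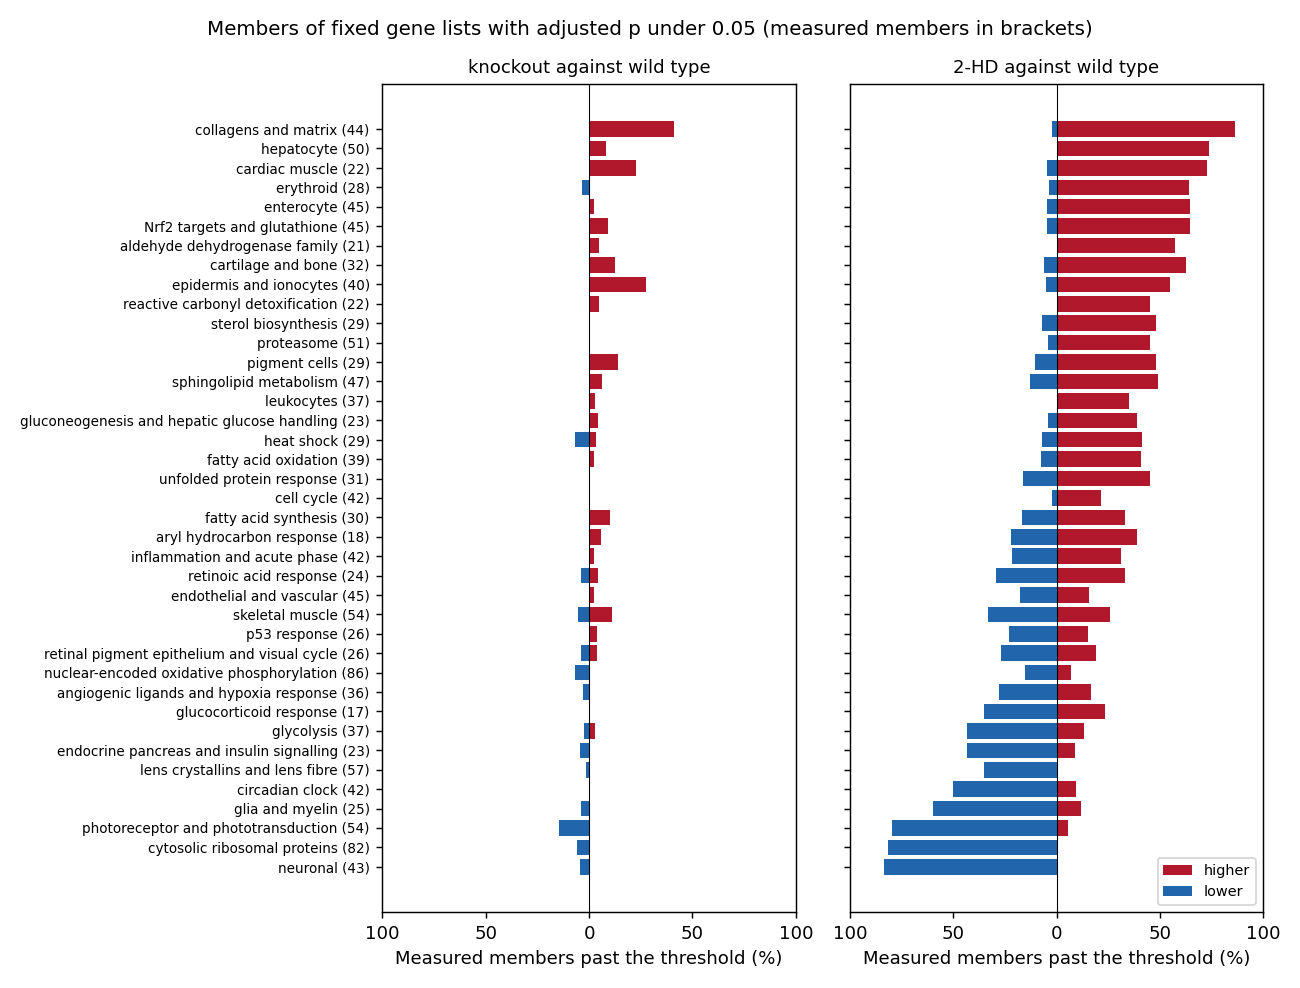
Percentage of the measured members of fixed gene lists (number measured in brackets) that were called higher (red, to the right) or lower (blue, to the left) at an edgeR adjusted p under 0.05, for knockout (n = 3) and 2-HD (n = 5) against wild type (n = 5); lists with at least 8 calls with 2-HD are drawn. Of 44 collagen and matrix genes 18 rose in the knockout and 38 with 2-HD, and of 54 photoreceptor genes 8 and 43 fell. Mean log2 fold changes were 0.43 and 0.74 for the matrix list and -0.53 and -0.54 for the photoreceptor list. Counts from groups of different size do not compare sizes of effect.

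Treatment with 2-HD, asked here against untreated wild type, gave more calls than the knockout, with 5 libraries instead of 3. Counts of calls depend on the number of libraries and do not compare sizes of effect. The mean log2 fold change of photoreceptor genes was -0.53 in the knockout and -0.54 with 2-HD, and that of epidermis genes 0.47 and 0.49. Matrix genes had means of 0.43 and 0.74, and neuronal genes -0.21 and -0.48. With 2-HD, 38 of 44 measured genes of the matrix, 37 of 50 of the liver, 18 of 28 of red blood cells and 16 of 22 of heart muscle were higher, and 36 of 43 neuronal, 43 of 54 photoreceptor and 67 of 82 ribosomal protein genes were lower. Within the limits used for the knockout (symbol, average expression and no overlap of libraries), the largest rise was that of hpxa, the gene of the haem-binding plasma protein hemopexin, from 0.693 ± 0.410 to 7.51 ± 4.29 CPM (SD, n = 5 and 5; log2 fold change 3.42, SE 0.44, edgeR adjusted p = 7.35e-05). Within these limits, the largest fall was that of pde6ha, an inhibitory subunit of the cone phosphodiesterase, from 108 ± 23.4 to 15.5 ± 13.2 CPM (-2.80, SE 0.38, edgeR adjusted p = 9.16e-05). Within the treated group, 2-HD replicate 1 had 38.9 CPM of pde6ha and the other 4 libraries 7.43 to 12.5 CPM. In all, 9398 of 22158 genes were called (42.4%), 5030 higher and 4368 lower. More than 2-fold changes were rarer, with 945 genes higher and 293 lower. Against a change of 1.2-fold instead of 0, 4839 genes were called.

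Further large rises were those of the transcription factor gene bhlha9 (log2 fold change 2.77), odam (2.71), enam (2.4) and scpp5 (2.35), which encode secretory proteins of mineralised tissue, and col10a1a (2.52). They also included barx2 (2.34), the apolipoprotein gene apoa4a (2.27), the row named LCT, the symbol of lactase (2.24), and muc13a (2.23). Falls included the nuclear receptor gene rorcb (-2.34) and nfil3-6 (-2.33), both tied to the circadian clock, and the calcium-sensor gene of photoreceptors guca1c (-1.83). The remainder were ppm1na (-2.12), the immediate early gene fosaa (-1.94), the metalloprotease gene mep1b (-1.90), dusp5, a phosphatase of MAP kinases (-1.88), the phosphodiesterase gene pde5aa (-1.78) and gpr186 (-1.76). The highest adjusted p among these 20 genes was 0.00208, that of mep1b.

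Collagen and matrix genes were again the list with the largest share of rises, with 38 of 44 higher and 1 lower (40 and 1 adjusted over the list alone) and a camera adjusted p of 1.96e-19. Among them mmp2 rose from 57.5 ± 5.65 to 116 ± 10.96 CPM, the fibrillin gene fbn2b from 25.3 ± 3.66 to 59.8 ± 3.69 CPM and the basement membrane collagen gene col4a5 from 152 ± 16.0 to 298 ± 17.9 CPM. Hepatocyte genes had 37 of 50 higher and 0 lower (38 and 1 adjusted over the list alone), among them the transferrin gene tfa (1259 ± 279.7 to 2608 ± 327 CPM) and apoba (53.9 ± 17.1 to 188 ± 42.1 CPM), with a camera adjusted p of 6.64e-12. Erythroid genes had 18 of 28 higher and 1 lower (19 and 1 adjusted over the list alone), with a camera adjusted p of 8.68e-06. They included urod of haem synthesis (log2 fold change 1.11), the spectrin gene sptb (0.74) and the band 3 gene slc4a1a (25.3 ± 4.74 to 71.1 ± 20.5 CPM). Cardiac muscle genes had 16 of 22 higher and 1 lower (16 and 1 adjusted over the list alone), including myl7 (1.17), tnnc1a (1.72) and myl4 (1.22), with a camera adjusted p of 9.58e-05. Leukocyte genes had 13 of 37 higher and 0 lower (13 and 0 adjusted over the list alone), including mpeg1.2 (1.82), csf1ra (1.13) and rac2 (0.60), with a camera adjusted p of 0.0120. The adjusted p with an estimated correlation was 0.386 for leukocytes and 0.344 for the other 4 lists. Without wild type replicate 14 and 2-HD replicate 1, 36 matrix, 36 hepatocyte, 14 erythroid, 13 cardiac and 12 leukocyte genes rose.

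Aldehyde dehydrogenases rose with 2-HD, with 12 of 21 higher and 0 lower (12 and 0 adjusted over the list alone), a camera adjusted p of 0.00258, and an adjusted p of 0.344 with an estimated correlation. The largest rise was that of aldh3a2b, a fatty aldehyde dehydrogenase gene, from 9.08 ± 2.08 to 20.6 ± 3.43 CPM (log2 fold change 1.18, SE 0.16, edgeR adjusted p = 8.42e-05). The others besides aldh3b1 were aldh1a3 (0.64), aldh1l2 (0.61), aldh2.2 (0.58), aldh16a1 (0.53), aldh1a2 (0.50), aldh1l1 (0.36), aldh3a2a (0.28), aldh7a1 (0.28), aldh8a1 (0.25) and aldh5a1 (0.20). The call of aldh5a1 was lost without wild type replicate 13 (adjusted p = 0.0523), and that of aldh3a2a without wild type replicates 10 (0.0712) or 14 (0.0568) or 2-HD replicates 3 (0.0719) or 5 (0.0719). The call of aldh8a1 was lost without wild type replicates 3 (0.0604), 10 (0.113) or 13 (0.0985), and without each 2-HD replicate (adjusted p = 0.0567 to 0.0867). Without wild type replicate 14 and 2-HD replicate 1, the family had 10 of 21 higher and 1 lower (camera adjusted p = 0.00796). Genes of reactive carbonyl detoxification had 10 of 22 higher and 0 lower (10 and 0 adjusted over the list alone), including the carbonyl reductase genes cbr1 (0.95) and cbr1l (0.83) and sod3a (1.00). Nrf2 targets and glutathione genes had 29 of 45 higher and 2 lower (29 and 2 adjusted over the list alone), with aifm4 (1.09) and abcc2 (1.02) higher and tkta (-0.67) lower. Sphingolipid genes had 23 of 47 higher and 6 lower (24 and 6 adjusted over the list alone), with gba2 (0.69) and sptlc3 (0.92) higher and s1pr1, the sphingosine 1-phosphate receptor gene of vessels (-0.59), lower. Camera adjusted p-values of these 3 lists were 0.00474, 0.000314 and 0.000636, and the adjusted p was 0.344 for each with an estimated correlation. Without wild type replicate 14 and 2-HD replicate 1, they had 11 higher and 0 lower, 24 and 4, and 26 and 6, in this order.

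Lists of glucose metabolism moved in different directions. Glycolysis genes had 5 of 37 higher and 16 lower (5 and 16 adjusted over the list alone), with a camera adjusted p of 0.00983. Among them pgam2 (-0.69) and pkmb (-0.68) fell, and slc2a1b, a glucose transporter gene, rose (16.0 ± 1.96 to 27.9 ± 2.69 CPM). Genes of gluconeogenesis and hepatic glucose handling had 9 of 23 higher and 1 lower (9 and 1 adjusted over the list alone), with a camera adjusted p of 0.0132. They included pck2 (133 ± 20.1 to 234 ± 18.7 CPM), and slc37a4a (0.86) and g6pca.1 (0.83) of the glucose 6-phosphatase system. Genes of the endocrine pancreas and insulin signalling had 2 of 23 higher and 10 lower (2 and 10 adjusted over the list alone), with a camera adjusted p of 0.0124, and neurod1 (-1.09), pax6b (-0.69) and igf1rb (-0.48) fell. Both neurod1 and pax6b are also expressed in the nervous system and retina. With an estimated correlation the adjusted p was 0.344 for each of the 3 lists. Sterol biosynthesis genes had 14 of 29 higher and 2 lower (14 and 2 adjusted over the list alone), including sc5d (1.49) and dhcr7 (0.77), with a camera adjusted p of 0.00664 and an adjusted p of 0.614 with an estimated correlation. Without wild type replicate 14 and 2-HD replicate 1, 19 of 28 sterol genes were higher and 2 lower. Glycolysis then had 6 higher and 19 lower, gluconeogenesis 10 and 2, and endocrine pancreas 1 and 10.

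Neuronal genes had 0 of 43 higher and 36 lower (1 and 36 adjusted over the list alone), with a camera adjusted p of 2.36e-17. The synaptic genes syt1a and syn2a changed from 488 ± 29.1 to 304 ± 24.3 CPM and from 127 ± 5.35 to 85.9 ± 8.31 CPM, and gad1b of GABA synthesis from 269 ± 20.6 to 168 ± 21.5 CPM. Photoreceptor and phototransduction genes had 3 of 54 higher and 43 lower (4 and 43 adjusted over the list alone), including prph2b (-0.79) and rcvrn2 (-0.96) besides pde6ha, with a camera adjusted p of 5.32e-10. Genes of the retinal pigment epithelium and visual cycle had 5 of 26 higher and 7 lower (5 and 7 adjusted over the list alone) and were not called as a list (camera adjusted p = 0.110). Of these rbp3, the retinoid carrier gene between photoreceptors and pigment epithelium, fell from 364 ± 84.0 to 115 ± 21.6 CPM, rdh8b fell (-1.49) and lrata rose (1.22). Cytosolic ribosomal protein genes had 0 of 82 higher and 67 lower (1 and 68 adjusted over the list alone), with a camera adjusted p of 1.69e-12 and small changes such as those of rps29 (-0.42) and rpl38 (-0.54). The adjusted p with an estimated correlation was 0.386 for the ribosomal list and 0.344 for the neuronal and photoreceptor lists. Endothelial and vascular genes went both ways, with 7 of 45 higher and 8 lower (4 and 6 adjusted over the list alone), and were not called as a list (camera adjusted p = 0.697, direction down, with a median of 0.02 and a mean of 0.03 on the log2 scale). Among them she rose (0.87), and s1pr1 (-0.59) and the peptide ligand gene apln (-0.48) fell. Without wild type replicate 14 and 2-HD replicate 1, 36 neuronal, 41 photoreceptor and 76 ribosomal protein genes fell.

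**Figure D3:**
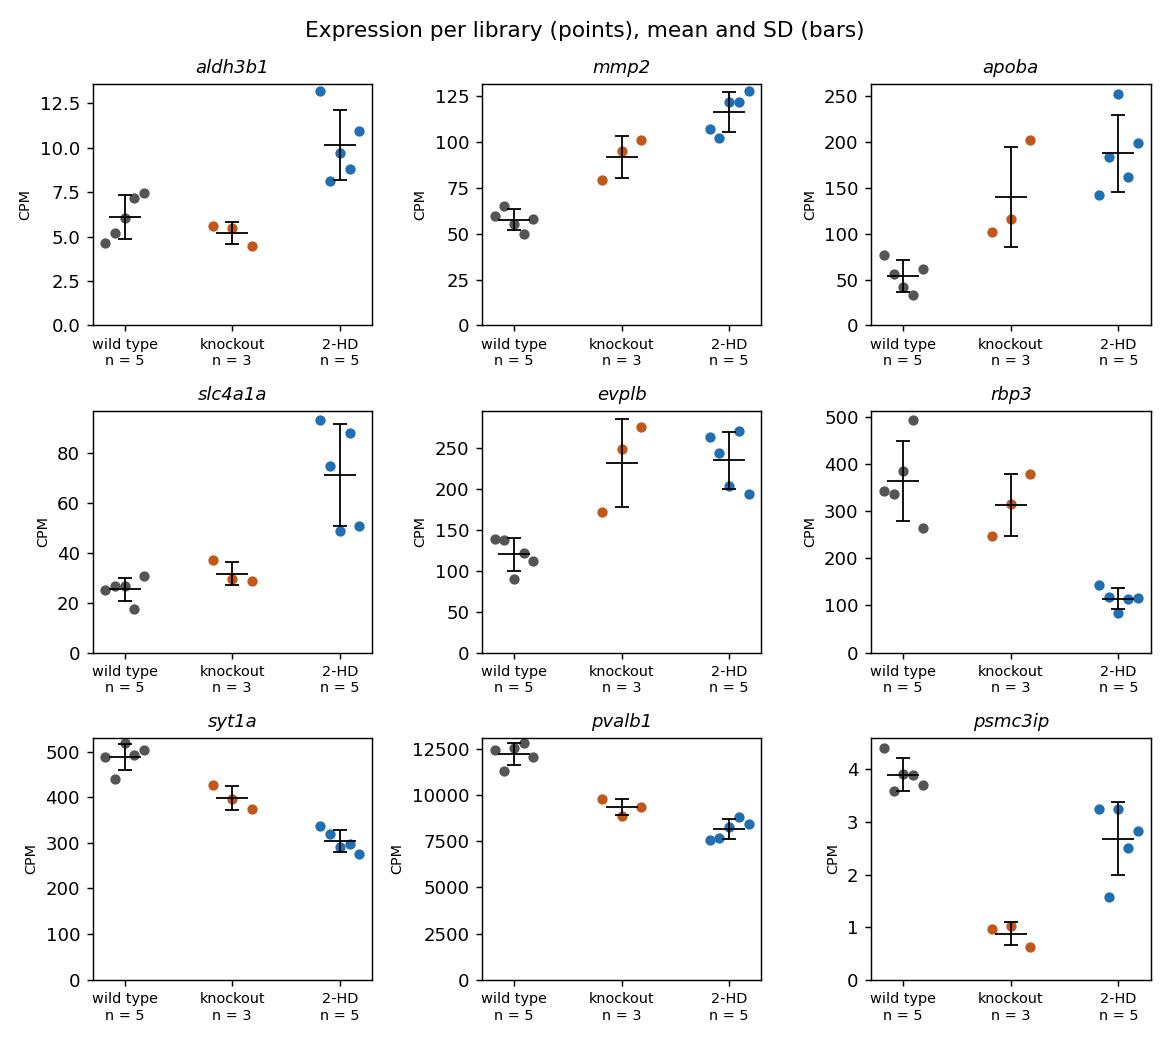
Expression of 9 genes in CPM (y axis, from 0) in wild type (n = 5), knockout (n = 3) and 2-HD (n = 5); points are libraries, the long horizontal bars the mean and the whiskers the SD. The matrix gene mmp2 has means of 57.5, 91.7 and 116 CPM in the 3 groups, whereas psmc3ip is lowest in the knockout at 0.875 CPM and rbp3 lowest with 2-HD at 115 CPM.

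Most genes called in the knockout were also called with 2-HD, and in the same direction, when both were set against the same 5 wild-type libraries. Of the 909 genes higher in the knockout 844 were also higher with 2-HD, and of the 413 lower genes 333 were also lower, whereas 2 genes were called in opposite directions. Independent lists of these sizes would share 206 and 81.4 genes. Simulated groups without changes made 0.05 knockout calls on average, too few to show what the shared controls add to this number. Across genes, which are not independent replicates, the fold changes of the comparisons had a Pearson correlation of 0.680, and simulated unchanged groups gave 0.439. The covariance was 0.145, against 0.0245 in the simulations, a difference of 0.121. With the wild-type libraries split so that the comparisons shared none, the correlation averaged 0.465 over 20 splits, with a range of 0.366 to 0.605, and the covariance 0.116. The number of genes called in both and in the same direction then averaged 313 and ranged from 0 to 1273. Knockout calls in these splits averaged 483 and ranged from 0 to 2433, and independent lists would share 44.6 higher and 20.7 lower genes on average.

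**Figure D4:**
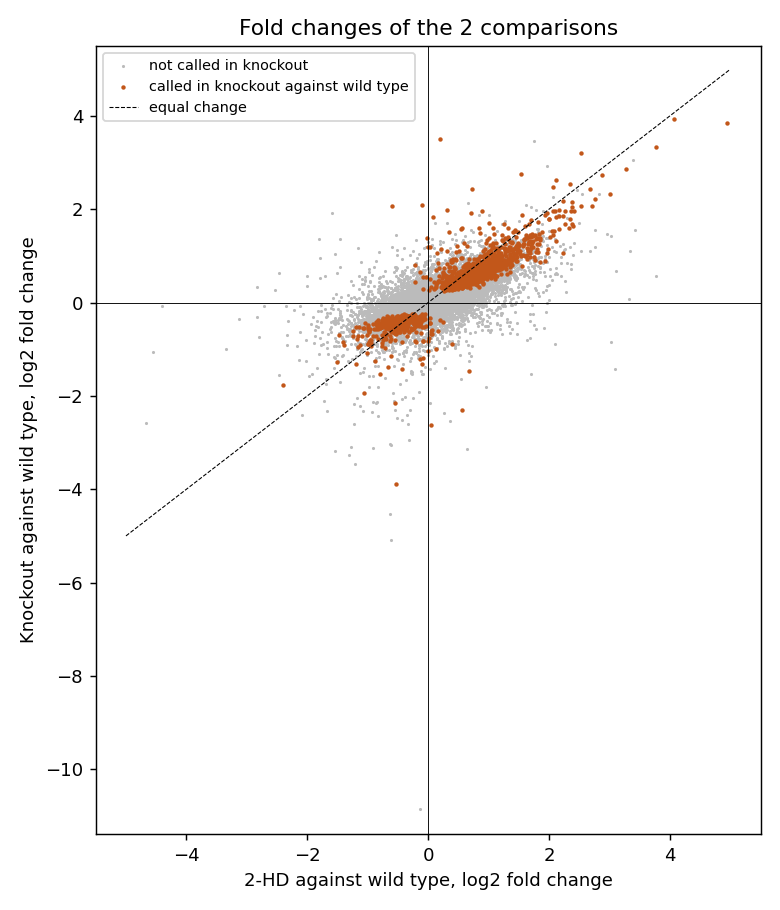
Log2 fold change of each of 22158 genes with 2-HD against wild type (x axis) and in the knockout against wild type (y axis); orange points are the 1322 genes called in the knockout, and the dashed line marks equal change. Most orange points lie in the quadrants of equal sign, where 1295 of the 1322 genes fall, and both axes use the same 5 wild-type libraries, which alone give a positive correlation.

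The direct comparison of knockout with 2-HD asked where these groups differ, and its wild-type controls cancel. Of the measured genes 10 of 28 of red blood cells, 10 of 29 of sterol synthesis, 12 of 51 of the proteasome and 8 of 44 of the matrix were lower in the knockout than with 2-HD, and 10 of 43 neuronal genes were higher. Among called genes within the same limits of symbol, expression and overlap, the highest were ppp1r27b (0.588 ± 0.533 CPM with 2-HD and 2.87 ± 0.184 CPM in the knockout), pde6ha (15.5 ± 13.2 and 64.8 ± 11.2 CPM), rorcb, the neuropeptide gene npvf and ppm1na, with log2 differences of 2.28, 2.06, 1.64, 1.57 and 1.49. The lowest were the ferritin gene fthl29 (-4.51), guca1a (-2.45), the nuclear receptor gene nr1d4a (-2.45), eevs (-2.23) and the second row of hbae1.3 (-2.15). Of these nr1d4a stood at 22.8 ± 6.11 CPM with 2-HD and 4.18 ± 1.31 CPM in the knockout (edgeR adjusted p = 0.00537). The SD of fthl29 with 2-HD (9.16 CPM) exceeded its mean (8.78 CPM), and fthl29 is among the 200 measured genes nearest aldh3b1. Of these 10 genes and aldh3b1, 8 lost their call without knockout replicate 3, 6 without replicate 7, 4 without replicate 2, 3 without each of 2-HD replicates 2 to 5 and 0 without 2-HD replicate 1. Those of ppp1r27b, rorcb and ppm1na were lost without any 1 of these libraries except 2-HD replicate 1 (adjusted p 0.0585 to 0.0850, 0.0603 to 0.154 and 0.0502 to 0.0968), and that of fthl29 without each knockout library (0.0524 to 0.0706). Without knockout replicate 3 the calls of npvf (0.0638), pde6ha (0.0638) and eevs (0.0523) were lost too, and that of npvf also without replicate 7 (0.0640). In all, 1547 genes differed, 870 higher and 677 lower in the knockout.

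Erythroid genes had 0 of 28 higher and 10 lower (0 and 17 adjusted over the list alone) in the knockout against 2-HD, sterol biosynthesis genes 0 of 29 higher and 10 lower (0 and 22 adjusted over the list alone) and collagen and matrix genes 0 of 44 higher and 8 lower (1 and 13 adjusted over the list alone). Proteasome genes had 2 of 51 higher and 12 lower (2 and 33 adjusted over the list alone), and neuronal genes 10 of 43 higher and 0 lower (25 and 0 adjusted over the list alone). Camera adjusted p-values were 3.73e-11, 3.73e-11, 9.47e-09, 3.73e-11 and 2.50e-11 in this order. With an estimated correlation the adjusted p was 0.696 for the erythroid, sterol and neuronal lists and 0.732 for the proteasome and matrix lists. Photoreceptor genes had 3 of 54 higher and 3 lower (4 and 4 adjusted over the list alone) and were not called as a list (camera adjusted p = 0.401). The count of 1547 changed to 231, 81 and 409 without knockout replicates 2, 3 and 7, and to 3229, 863, 576, 624 and 581 without 2-HD replicates 1 to 5. Without wild type replicate 14 and 2-HD replicate 1 together, it was 3494, with 23 sterol, 30 proteasome, 11 erythroid and 9 matrix genes lower and 24 neuronal genes higher.

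The genes around aldh3b1 were compared with the rest of the genome. Of the 200 measured genes nearest to it, 33 were called in knockout against wild type (16.5%), 16 higher and 17 lower, against 6.0% of 17866 other genes (odds ratio 3.1, 95% interval 2.05 to 4.54, Fisher's exact test, two-sided p = 1.71e-07). In knockout against 2-HD 19.5% were called, against 7.16% elsewhere (odds ratio 3.14, Fisher's exact p = 1.37e-08). In 2-HD against wild type, where both groups are labelled wild type, 49.0% were called, against 44.1% elsewhere (odds ratio 1.22, 95% interval 0.913 to 1.63, Fisher's exact p = 0.174). Fisher's test takes genes as independent, which neighbouring genes need not be, so these p-values may be too small and the intervals too narrow. Genes of known position that differed in the knockout from both other groups in the same direction numbered 8 near aldh3b1 and 28 elsewhere, the rest of the same chromosome included. They made up 4.0% of the 200 genes, 0.706% of 708 further genes of the same chromosome and 0.157% of all 17866 other genes.

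**Figure D5:**
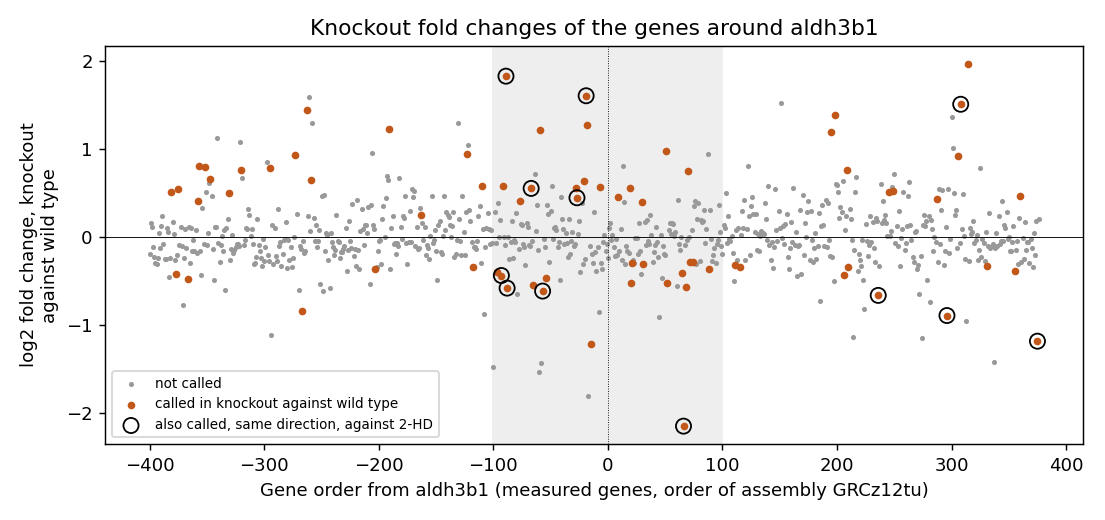
Log2 fold change in the knockout (n = 3) against wild type (n = 5, y axis) of measured genes by their order from aldh3b1 (x axis, order in assembly GRCz12tu); orange points are called genes, circles mark those also called in the same direction against 2-HD, and grey shading covers the 200 nearest genes. Of these 200 genes 33 were called and 8 are circled, psmc3ip and casp6b.1 among them.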

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

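Of the tests given here, the 2 estimates of mixing were chosen after the result was seen. Single libraries stood apart from the other 4 of their group in 13 of 288 groups of values, by a gap to the nearest library that took a large share of the group's range. Chance alone gives about 1 in 20 such groups. In 2-HD replicate 1, pde6ha stood at 38.9 CPM against 7.43 to 12.5 CPM (gap share 0.840), rorab at 98.5 CPM against 65.3 to 73.7 CPM (0.746) and slc22a21 at 11.7 CPM against 7.79 to 8.89 CPM (0.719). In wild type replicate 14, abcb6a stood at 8.95 CPM against 4.52 to 5.54 CPM (0.770) and aldh1l1 at 91.4 CPM against 70.18 to 74.5 CPM (0.797). The total of that library was 17975289 counts against 18845611 to 19009200 in the other wild types (0.845). In wild type replicate 13, npvf stood at 7.08 CPM against 3.91 to 4.24 CPM (0.894) and aldh5a1 at 24.0 CPM against 27.4 to 28.6 CPM (0.737). In wild type replicate 5, psme4a stood at 20.9 CPM against 40.5 to 47.8 CPM (0.729) and cbr1l at 57.9 CPM against 36.7 to 42.7 CPM (0.717). In wild type replicate 10, gad1b stood at 305 CPM against 254 to 268 CPM (0.729). In 2-HD replicate 3, pgam2 stood at 58.6 CPM against 68.0 to 70.33 CPM (0.804), and the total of 2-HD replicate 2 was 19482661 counts against 19339056 to 19376119 in the others (0.714).

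Wild type replicate 14 and 2-HD replicate 1 held 6 of the 13 values, and their deviations from their group means had a Pearson correlation of 0.483 across genes, which are not independent replicates, the highest of all pairs of libraries from different groups. Exchanging the 2 labels left 9 genes called in 2-HD against wild type, where 9398 were called with the labels as given, which argues against exchanged labels. RNA of 1 library in the other would need 1 mixing share, and 2-HD replicate 1 in wild type replicate 14 gave median shares of 0.668 (quartiles 0.236 to 0.944, 67 genes seen in the source library alone) and 0.0129 (-0.112 to 0.176, 205 genes that separate the groups), which argues against that direction. The opposite direction gave 0.595 (0.235 to 1.000, 90 genes) and 0.316 (0.146 to 0.489, 442 genes), quartiles that overlap, so wild type replicate 14 RNA in the 2-HD replicate 1 library stays open. Of the 200 genes deviating most in both libraries, 61 had another of the 200 among the 5 nearest measured genes on either side, against a median of 20 and a highest value of 44 in 1000 random sets, and 23 and 46 for the 200 genes with the smallest p and the largest fold with 2-HD. Parents or haplotypes shared by larvae of these 2 libraries are therefore a candidate explanation that stays open beside such mixing, the labels name no parents, and no biological explanation from the design was tested.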

How the results depend on the processing

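The settings without wild type replicate 14 and 2-HD replicate 1 together, and without the 200 genes nearest aldh3b1, were chosen after the result was seen. The 1322 calls of knockout against wild type changed to 102 with only these groups in the fit, 65 against a 1.2-fold change, 2399 with DESeq2 and 3573 with limma-voom. The 9398 calls with 2-HD changed to 4839 against a 1.2-fold change. The 1547 calls of knockout against 2-HD changed to 38 against a 1.2-fold change, 2377 with DESeq2, 4611 with limma-voom, 2677 with a surrogate variable and 3494 without both libraries. With 1 library left out the counts ranged from 3 to 2071 for knockout against wild type (without knockout replicate 3 and wild type replicate 3), from 8120 to 9968 for 2-HD and from 81 to 3229 for knockout against 2-HD (without knockout replicate 3 and 2-HD replicate 1). Under RLE and upper-quartile factors, both other filters and without the 200 neighbours of aldh3b1, each count stayed within 1.5 times of its value. A test against a 1.2-fold change is stricter by construction, and the cause of the other changes was not tested.

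No label says that equal numbers pair the libraries. The correlations of deviations across genes for equal numbers were 0.264, 0.0955, 0.0399, 0.0591 and -0.00416, and not every library correlated best with its own number. Several libraries have a number that no other library has, so this cannot decide whether numbers mark pairs, and pairing stays open. With the number in the label as a replicate block, 2, 4230 and 333 genes were called in knockout against wild type, 2-HD against wild type and knockout against 2-HD. A library whose number no other library has adds nothing to a comparison under the block, so these fits rest on few libraries. Their low counts therefore do not show that the calls are fragile. Under the block the log2 fold change of aldh3b1 in the knockout turned to 0.34 (edgeR adjusted p = 0.773), also not past the threshold. Replicate 3 is the only number found in both wild type and knockout, and there aldh3b1 stood at 4.62 and 5.49 CPM, the direction seen under the block.

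Camera called 21, 28 and 16 of 43 lists in the same order of comparisons. With an estimated correlation 0, 0 and 0 were called, with lowest adjusted p-values of 0.413, 0.344 and 0.696, and fry, which does not compare a list with other genes, called 12, 30 and 2. With 1 library left out camera called 20 to 23, 27 to 30 and 12 to 21 lists. The 1177 genes called in the same direction in both comparisons with wild type averaged 313 when the wild types were split, where each fit has fewer samples.

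For genes tracked by the naming rule in knockout against wild type, 803 of 1140 values over the alternatives kept their direction and side of the threshold, 336 kept their direction and lost the call and 1 turned, that of aldh3b1. For 2-HD against wild type 1788 of 1827 kept both and 39 lost the call, and for knockout against 2-HD 168 of 209 and 41. At this depth aldh3b1 rested on 86 to 129 counts in each wild-type or knockout library, and its 95% interval in the knockout leaves changes from -0.63 to 0.17 on the log2 scale open.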

Other observations

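Of the tests given here, those of scaling, of time of day and of the genes near aldh3b1 were chosen after the result was seen. Camera called further lists in the knockout against wild type that had few or no called members. Enterocyte genes had 1 of 45 higher and 0 lower (15 and 0 adjusted over the list alone), lens genes 0 of 57 higher and 1 lower (0 and 1 adjusted over the list alone), with crygm2d5 lower (-0.63 on the log2 scale), and circadian clock genes 0 of 42 higher and 0 lower (0 and 0 adjusted over the list alone). Histone genes had 0 of 14 higher and 1 lower (0 and 1 adjusted over the list alone), genes of glia and myelin 0 of 25 higher and 1 lower (0 and 2 adjusted over the list alone) and those of reactive carbonyl detoxification 1 of 22 higher and 0 lower (3 and 0 adjusted over the list alone). Camera adjusted p-values were 9.05e-07, 2.33e-07, 0.000322, 0.00178, 0.00779 and 0.0145 in this order, with an adjusted p of 0.413 for each with an estimated correlation. Sterol genes had 0 of 29 higher and 0 lower (0 and 0 adjusted over the list alone) and glycolysis genes 1 of 37 higher and 1 lower (1 and 0 adjusted over the list alone). Their lists had camera adjusted p-values of 0.0145 and 0.0422, direction down, and adjusted p-values of 0.632 and 0.413 with an estimated correlation. Camera calls were lost without knockout replicate 2 for the lens (0.0912), carbonyl (0.106) and glycolysis lists (0.0541). That of glycolysis was also lost without knockout replicate 3 (0.107) or wild type replicates 5 (0.111) or 10 (0.0625), and that of sterol synthesis without knockout replicate 7 (0.0842) or wild type replicate 5 (0.0589).

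With 2-HD, enterocyte genes had 29 of 45 higher and 2 lower (29 and 3 adjusted over the list alone), cartilage and bone genes 20 of 32 higher and 2 lower (22 and 2 adjusted over the list alone), epidermis and ionocyte genes 22 of 40 higher and 2 lower (22 and 2 adjusted over the list alone) and pigment cell genes 14 of 29 higher and 3 lower (14 and 3 adjusted over the list alone). Proteasome genes had 23 of 51 higher and 2 lower (25 and 2 adjusted over the list alone), among them psmd2 (0.70), psme4a (-1.09) and psmd7 (0.43), genes of fatty acid oxidation 16 of 39 higher and 3 lower (18 and 3 adjusted over the list alone), heat shock genes 12 of 29 higher and 2 lower (12 and 2 adjusted over the list alone) and cell cycle genes 9 of 42 higher and 1 lower (8 and 1 adjusted over the list alone). Camera adjusted p-values of these 8 lists were 4.40e-06, 2.40e-05, 0.000247, 0.00865, 0.00126, 0.0110, 0.0309 and 0.0231, direction up, and adjusted p-values with an estimated correlation 0.386, 0.386, 0.422, 0.386, 0.621, 0.386, 0.431 and 0.694. The call of the heat shock list was lost without 2-HD replicate 3 (0.0614) or wild type replicate 10 (0.0501), and that of the cell cycle list without 2-HD replicates 3 (0.0603) or 5 (0.0563). Lens genes had 0 of 57 higher and 20 lower (0 and 18 adjusted over the list alone), genes of glia and myelin 3 of 25 higher and 15 lower (3 and 17 adjusted over the list alone), circadian clock genes 4 of 42 higher and 21 lower (6 and 22 adjusted over the list alone) and histone genes 0 of 14 higher and 6 lower (0 and 6 adjusted over the list alone). Genes of the p53 response had 4 of 26 higher and 6 lower (4 and 6 adjusted over the list alone), among them cdkn1a (1.35), a cell cycle inhibitor gene, and were not called as a list (camera adjusted p = 0.990). Among clock genes roraa (-0.88) and rorab (-0.90) fell. Camera adjusted p-values of the lens, glia, clock and histone lists, direction down, were 9.58e-05, 0.000435, 0.00139 and 0.00802, and the adjusted p-values with an estimated correlation 0.526, 0.344, 0.437 and 0.344.

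Along the first principal component, expression shifted from wild type through the knockout to 2-HD. Not every list followed this order. Mean log2 fold changes in the knockout and with 2-HD were 0.43 and 0.74 for matrix genes, which did. They were -0.20 and 0.52 for sterol genes and -0.16 and -0.07 for oxidative phosphorylation genes, which did not. A wrong scaling factor would move each gene of a comparison alike and add no covariance across genes. The knockout and 2-HD fold changes had a covariance of at least 0.0930 (range of the 20 splits to 0.149) with no wild type shared. Any change shared by both comparisons that varies between genes would give this, so it argues only against 1 constant factor as the whole cause. It does not test effects of scaling or library composition that differ between genes. Of 2 earlier tests of scaling, RLE and upper-quartile factors moved the median log2 fold change by at most 0.0204, and the rarer direction held at least 31.2% of calls, which the centring of fold changes largely fixes, so both decide nothing. Across genes, which are not independent replicates, the first principal component of the 5 wild types alone had an absolute Pearson r of 0.0799 with the knockout against 2-HD fold changes, under the bound of 0.1 set before the test, but that bound was wrong, since wild type replicate 14 alone held 69.6% of the component's sum of squares and the fourth component had a Spearman correlation of -0.200, so variation such as stage cannot be told apart from the groups. Time of day at collection cannot be told apart from the groups: with 2-HD the medians of 14 dawn and 9 dusk clock genes were 0.00977 and -0.80, a log2 difference of 0.814 (permutation test, two-sided p = 0.0801, adjusted p = 0.120 over 3 comparisons), against -0.08 in the knockout (p = 0.421, adjusted p = 0.421) and -0.86 between knockout and 2-HD (p = 0.00562, adjusted p = 0.0169). Totals per library did not overlap between the groups and rose in the order of the shift. TMM factors averaged 0.963 in wild type, 1.01 in the knockout and 1.03 with 2-HD. Whether such differences between libraries contribute to the shift was not tested. Genotype and treatment, which the design names, may also underlie the shift and stay open, as do clutch and day of collection, which the labels do not give.

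Genes that differed in the knockout clustered near aldh3b1, with an odds ratio of 3.1 for a call among the 200 nearest genes. Genes that differed from both other groups in the same direction numbered 8 there, and 0% of 12358 windows on other chromosomes held as many, the highest other count being 3, which argues against a chance position. A haplotype carried along with the knockout allele is a candidate explanation, under which psmc3ip, casp6b.1 and other neighbours may differ without any effect of aldh3b1 itself. An effect of the knockout on its neighbours stays open and was not tested. Without these 200 genes 1265 genes were called in knockout against wild type, and that count keeps genes further along the same chromosome.

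Other splits of the same libraries were also counted. For knockout against wild type 1 of 56 splits, the real one, gave as many genes (1322, against at most 591 in another, which set wild type replicates 10, 13 and 14 against the rest). For 2-HD against wild type it was 1 of 100 drawn of 126 (9398 against at most 3933), and for knockout against 2-HD 1 of 56 (1547 against at most 61). For each of the 3 counts the real split was thus past a share of 0.05. This takes the libraries as independent, which the labels do not show. It argues against a random assignment of independent libraries only, since a clutch or day shared within a group would also set the real split apart.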
